A study of Mus musculus with 7 samples.

How the data were processed

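RNA was measured in vascular fragments of the brain from female C57BL/6N mice aged 12 weeks. Mice had been injected into the cerebral ventricles with PDGF-CC, a growth factor that binds the receptor PDGFR-alpha, or with phosphate-buffered saline (PBS), and were killed 4 hours later. There were 4 PDGF-CC samples and 3 PBS samples, each on 1 microarray. Per the labels' protocols, 10 ng of total RNA per sample was amplified into cDNA from whole transcripts and labelled with biotin. The labels do not say whether each sample came from a separate mouse. P-values, apart from those of the main list test explained below, therefore measure the spread between these samples, which may in part be technical.

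The deposited values were on the log2 scale, as their range and nearly equal distributions in all 7 arrays showed. Affymetrix Expression Console, RMA and limma are named in the submitters' processing notes, without versions or order. RMA corrects background, sets the distribution of values equal between arrays and summarises the probes of a probe set by medians. Equalising distributions removes any difference in overall RNA level between groups. Pairs of arrays held exactly the same value for between 2527 and 4475 of the 33793 probe sets, and the origin of these equal values was not tested. The genome build and the settings are not given in the sources used here, and no coordinates are printed. Array data carry no read depth, and the number of arrays limits the precision.

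Gene names came from the platform annotation of the probe sets. Of 33793 probe sets, 23521 had 1 gene symbol, 1814 had several and 8458 had none. No gene is named from a probe set with several symbols. Older and newer symbols of the fixed lists were matched through RefSeq gene names of the assembly GRCm38.p6. Of 670 list entries, 629 had a probe set with that symbol alone, and the others were not analysed here. The erythroid list had fewer than 5 such genes and was not tested.

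Probe sets were tested if they had a gene symbol and a mean above the 30th percentile of such probe sets, a log2 value of 4.145. This left 17734 probe sets and 15582 genes with a single symbol. PDGF-CC was compared with PBS by lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates. Adjustment was by the Benjamini-Hochberg method with a threshold of 0.05. All limma tests were 2-sided. A looser count took probe sets at an unadjusted p under 0.01 with a difference of at least 1.5-fold.

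Before the data were examined, 38 gene lists were fixed, covering pathways and markers of cell types that vascular fragments can hold. Of these, 37 were tested with camera of limma, which compares a list with the other genes, at a preset correlation of 0.01 between genes. With that setting its p-values rest mostly on the spread between genes, taken as nearly independent, and less on that between samples. Estimated correlations in the lists it called ran from -0.035 (lymphocytes) to 0.597 (microglia), with 0.263 for the glucocorticoid list. Each gene entered with its brightest probe set. Camera with an estimated correlation and fry were run as alternatives. Members of a list were also adjusted over the list alone. For list means, an exact permutation test used all 35 splits of the 7 arrays into 4 and 3, and the smallest p it can give is 0.0286.

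The rule for named genes took the 10 largest rises and the 10 largest falls past the adjusted threshold with complete separation of the groups and a single symbol. Places left went to the smallest unadjusted p among separated probe sets changed at least 1.5-fold. Olfactory, vomeronasal, predicted and Rik genes were left out of that part. The rule then took every member of the list of PDGF ligands and receptors, and up to 4 members with the smallest p from each other list.

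Other filters, normalizations, weights, covariates and left-out arrays were tried as alternatives, and the closing section gives their effect. The fit was tested on simulated data for 17734 probe sets with the spread of these arrays. Noise was normal and independent between probe sets, and 50 probe sets each were changed 1.5-, 2-, 4- and 8-fold at once. Of these, the fit called 39, 46, 49 and 49 in that order, with 11 false calls over all. Large changes simulated together ease the adjusted threshold, so these shares do not carry over to data with few changed probe sets. Figures were drawn with matplotlib 3.10.9.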

Results

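The transcriptome of brain vascular fragments was compared between mice injected into the cerebral ventricles with PDGF-CC (4 arrays) and mice injected with PBS (3 arrays), 4 hours after injection. Vascular fragments are pieces of small vessels that hold endothelial cells, mural cells and attached cells of the brain. Values between arrays correlated at 0.987 to 0.994, and no array was a copy of another. The median residual SD of a probe set was 0.128 on the log2 scale. On the first principal component (28.5% of the variance) the arrays ran in the order of the numbers in their sample descriptions. Scores fell without a break from 24.4 for PDGF-CC array 1, which stood farthest out, to -14.9 for PBS array 3. On the second (23.3%) PBS array 2 stood apart. The sample descriptions carry numbers from 1 to 7 over both groups. PDGF-CC arrays had numbers 1, 2, 5 and 6, and PBS arrays 3, 4 and 7, so 2 PDGF-CC and 2 PBS arrays had numbers 1 to 4. Within 1 to 4 and within 5 to 7, every PDGF-CC number came before every PBS number. Differences within these parts, or with the parts as a block, therefore cannot separate treatment from the order within a part.

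The 3 transcripts with the smallest p were all at lower levels after PDGF-CC, but no probe set passed the adjusted threshold. Cdkn1a, a cyclin-dependent kinase inhibitor, differed by -1.07 ± 0.093 (log2, SE, n = 4 and 3), and Trp53inp1, a stress-induced regulator of autophagy and cell death, by -1.73 ± 0.15. The transcript 2810029C07Rik, named here after its values were seen, differed by -2.03 ± 0.16. All 3 had an adjusted p of 0.0549 by limma. The fit called 0 probe sets higher and 0 lower of 17734. At an unadjusted p under 0.05 there were 1071 probe sets, against 887 expected by chance, and at a p under 0.01 there were 190, against 177. At an unadjusted p under 0.01 with at least a 1.5-fold difference there were 47, of which 35 were lower and 12 higher in PDGF-CC, and 30 without PDGF-CC array 1. Among all tested probe sets, 444 were lower and 319 higher in every PDGF-CC array than in every PBS array. Together they made up 4.3% of probe sets, where chance gives 5.71%. With the filter at the 50th percentile, with a trended and robust prior, or with arrays centred on their median, 3 probe sets passed, all lower. Without PDGF-CC array 3, 1 probe set passed, again lower. Over the alternatives, adjusted p ranged from 0.0310 to 0.438 for Cdkn1a, from 0.0310 to 0.428 for Trp53inp1 and from 0.0104 to 0.428 for 2810029C07Rik.

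The 10 genes named for lower values were all below every PBS array in every PDGF-CC array, and none passed the adjusted threshold. Besides Cdkn1a and Trp53inp1 they included Sesn1, a sestrin that restrains mTORC1, at -0.62 ± 0.066 (adjusted p = 0.130). Ddit4, another inhibitor of mTORC1, differed by -1.37 ± 0.26, and Depp1, a regulator of autophagy, by -1.39 ± 0.24. Angptl4, a secreted inhibitor of lipoprotein lipase, differed by -1.76 ± 0.27. The others were Rgcc, a regulator of the cell cycle (-0.66 ± 0.081), the serotonin receptor gene Htr2a (-0.75 ± 0.12), the DNA repair nuclease gene Dclre1b (-0.66 ± 0.12) and Zdhhc23 (-0.75 ± 0.15). Apart from Cdkn1a and Trp53inp1, adjusted p for these genes lay between 0.130 and 0.722. Zdhhc23 was near the floor, with a PDGF-CC mean of 3.85, under the filter of 4.145, and a PBS mean of 4.59.

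Among the genes named for higher values, again without one past the adjusted threshold, was Il1a, which encodes the cytokine interleukin-1 alpha, at +0.91 ± 0.22. Transcription factor genes were Sox4, at +0.68 ± 0.12 and +0.63 ± 0.13 on its probe sets, and Hlx, at +0.67 ± 0.11. Ier5, an immediate-early gene, differed by +0.73 ± 0.18, and the inward rectifier potassium channel gene Kcnj2 by +0.67 ± 0.16. Gpr183, a receptor for oxysterols on immune cells, differed by +0.62 ± 0.17 and H2-T10, of the major histocompatibility complex, by +0.63 ± 0.10. Snord83b (+0.70 ± 0.18) and Mrgprh (+0.63 ± 0.18) completed the group, whose adjusted p lay between 0.623 and 0.769.

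**Figure D1:**
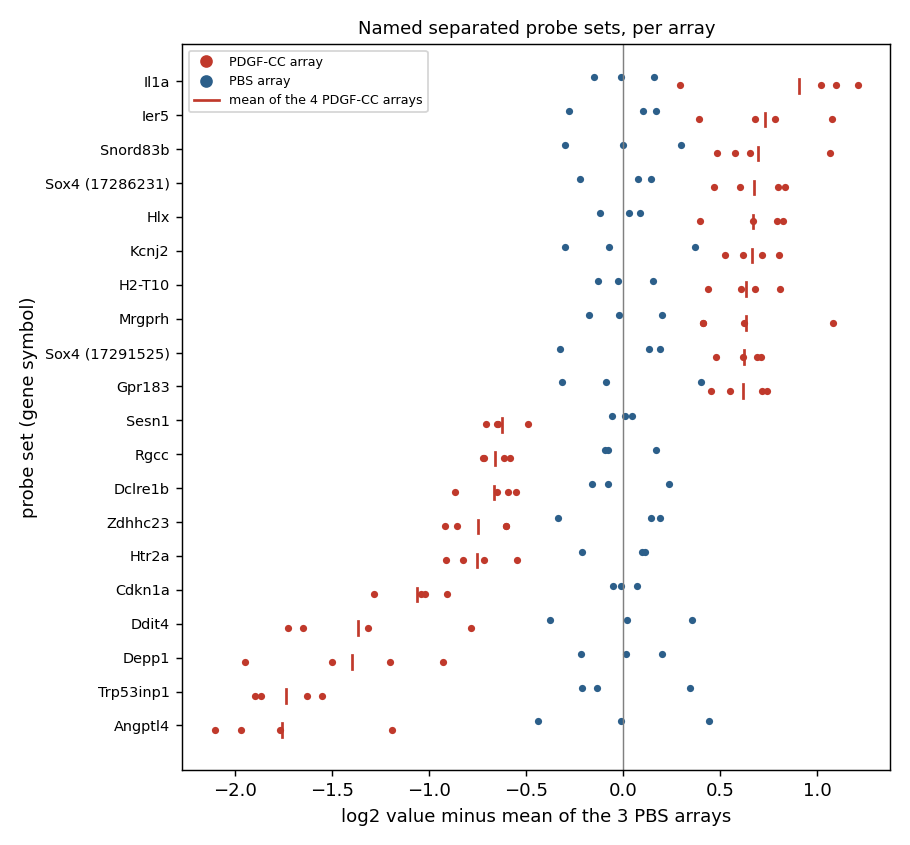
Log2 values of the 20 probe sets with the smallest unadjusted p among those separated and changed at least 1.5-fold, 10 per direction, with Rik and predicted genes such as 2810029C07Rik left out (rows), each minus the mean of the 3 PBS arrays, for every array; red points are PDGF-CC arrays, blue points PBS arrays, and red bars the PDGF-CC mean. The groups do not overlap in any row, which was required for a place here, and the mean differences run from -1.76 for Angptl4 to +0.91 for Il1a.

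Genes of the PDGF system itself differed little. Of 9 ligands, receptors and partners, none passed the adjusted threshold over all genes or over the list alone. Pdgfb was at +0.20 ± 0.058, Pdgfa at +0.11 ± 0.064, Pdgfc at +0.02 ± 0.054 and Pdgfd at -0.06 ± 0.079. The receptor genes Pdgfra and Pdgfrb were at -0.43 ± 0.26 and -0.05 ± 0.19. Pdgfra lay near the filter of 4.145, with means of 4.43 in PDGF-CC and 4.86 in PBS. Plat, which encodes the protease that activates PDGF-CC, was at -0.29 ± 0.11, Nrp1 at -0.26 ± 0.10 and Lrp1 at +0.16 ± 0.12. Without PDGF-CC array 1 Pdgfra was at -0.23, and without PBS array 3 at -0.25. Pdgfa was at +0.06 without PBS array 1, and Pdgfd ran from -0.03 without PDGF-CC array 2 to -0.13 without PDGF-CC array 4. Pdgfrb changed sign with the description number as a covariate (+0.06), without PDGF-CC array 1 (+0.03) and without PBS array 3 (+0.14), and was at -0.25 without PBS array 2. Without PBS array 2, Lrp1 was at -0.003 and Pdgfc at -0.01, while Lrp1 was at +0.25 without PBS array 3 and Pdgfc at +0.04 without PDGF-CC array 1. As a list they had a mean of -0.07 (camera adjusted p = 0.904), while fry's test for change in either direction gave an adjusted p of 0.0136.

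Immediate-early genes, which growth factors induce within minutes to hours, were higher as a list after PDGF-CC. Of 23 measured members 16 were positive, with a mean difference of +0.15 (camera adjusted p = 0.0113, and adjusted p = 0.536 with an estimated correlation). Fos was at +0.69 ± 0.21, Junb at +0.50 ± 0.14 and Fosb at +0.49 ± 0.15, while Ccn2, a matricellular protein gene, was at -0.58 ± 0.21. No member passed adjusted over the list alone. The call was lost without PDGF-CC array 2 (adjusted p = 0.0876) and without PBS array 1 (adjusted p = 0.101), with a range of 0.00420 to 0.536 over all alternatives. The mean was +0.23 within numbers 1 to 4 and +0.05 within 5 to 7. The ERK feedback list had a mean of +0.06 (adjusted p = 0.220), with Etv5 at +0.39 ± 0.16 (+0.60 without PBS array 1 and +0.23 without PBS array 2). The TGF-beta and BMP list had a mean of +0.09 (adjusted p = 0.0356, and adjusted p = 0.573 with an estimated correlation). Its members Id2 and Smad7 were at +0.36 ± 0.11 and +0.36 ± 0.15, the latter at +0.20 without PBS array 2. That call was lost without PBS array 1 (adjusted p = 0.133), PBS array 2 (0.306, mean +0.03) and PDGF-CC arrays 2 (0.0604), 3 (0.151) and 4 (0.0848). It was also lost without the filter on brightness (0.110) and, in an alternative chosen after seeing the data, with description numbers 1 to 4 against 5 to 7 as a block (mean +0.07, 0.143). The mean was +0.10 within numbers 1 to 4 and +0.02 within 5 to 7. Without PBS array 3 its mean was +0.15, and over all alternatives adjusted p ran from 0.000398 to 0.640.

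Glucocorticoid-responsive genes showed the largest shift of the fixed lists. Of 14 measured members 12 were negative, the mean difference was -0.63 and the median -0.65 (camera adjusted p = 1.37e-10). The call was lost with an estimated correlation (adjusted p = 0.536), in a range from 3.52e-12 over the alternatives. Fry's test for change in either direction gave an adjusted p of 0.00349, and its directional test 0.119. Adjusted over the list alone 9 were lower, against 0 over all genes. Pdk4, a brake on pyruvate oxidation, was at -0.89 ± 0.18, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, at -0.71 ± 0.16, and the clock gene Per1 at -0.98 ± 0.27. Cdkn1a and Ddit4 above belong to this list as well. Plin4 (+0.18 ± 0.097) and Zbtb16 (+0.08 ± 0.36), chosen after their values were seen, were the positive members. In every PDGF-CC array the list mean was below every PBS array, and the real grouping gave the largest mean of the 35 splits (exact permutation p = 0.0286, 2-sided, adjusted p = 0.352 over the lists). The mean was -0.70 within numbers 1 to 4 and -0.50 within 5 to 7. Choroid plexus markers were lower in the PDGF-CC arrays as well, with a mean of -0.49 over the list of choroid plexus and ependyma markers.

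Energy and protein production genes were lower as lists by small amounts. The respiratory chain list had a mean of -0.12, with 53 of 65 members negative (camera adjusted p = 1.22e-05, and adjusted p = 0.536 with an estimated correlation). Its largest difference was that of Cox8b, an isoform typical of muscle and brown fat, at -1.49 ± 0.35, and Ndufb3 was at -0.47 ± 0.16. The ribosomal protein list had a mean of -0.06, with 45 of 61 negative (adjusted p = 0.00697, and adjusted p = 0.536 with an estimated correlation). The heat shock list had a mean of -0.17, with 8 of 9 negative (adjusted p = 0.0103, and adjusted p = 0.536 with an estimated correlation), and Hspa1b was at -0.53 ± 0.27 (-0.34 without PDGF-CC array 1 and -0.35 without PBS array 2). Interferon-stimulated genes had a mean of -0.12 with all 14 negative (adjusted p = 0.00690, and adjusted p = 0.536 with an estimated correlation), and Rsad2 was at -0.27 ± 0.11 (-0.16 without PBS array 2). The hypoxia and glycolysis list had a mean of -0.14 with 11 of 12 negative (adjusted p = 0.0293, and adjusted p = 0.536 with an estimated correlation). Pfkfb3, an activator of glycolysis, was at -0.57 ± 0.15 and hexokinase gene Hk2 at +0.26 ± 0.092. The interferon call was lost without PBS array 2 (mean -0.04, adjusted p = 0.0826). The hypoxia call was lost without PDGF-CC arrays 1 (adjusted p = 0.0610) and 4 (0.0642) and without PBS arrays 1 (0.164) and 2 (0.125). It was also lost with the filter at the 50th percentile (0.0631) and with description numbers 1 to 4 against 5 to 7 as a block (0.0600), and its mean was -0.24 within numbers 1 to 4 and +0.01 within 5 to 7. Quantile normalization repeated over the tested probe sets ended the ribosomal (adjusted p = 0.126) and heat shock (0.0564) calls. Over all alternatives the lowest adjusted p was 4.95e-08 for respiratory chain, 0.00116 for ribosomal, 0.00223 for heat shock, 0.00180 for interferon and 0.00374 for hypoxia genes, and the highest was 0.536 for each.

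Markers of several cell types other than endothelium differed between the groups. Choroid plexus and ependyma markers had a mean of -0.49 and a median of -0.56 (camera adjusted p = 5.78e-05, and adjusted p = 0.536 with an estimated correlation). Adjusted over the list alone, 7 of 10 were lower, all of them among the 8 choroid plexus markers, whose mean was -0.621. The other 3 members, the measured ependyma markers among them, were positive. Kl, which encodes klotho, was at -1.14 ± 0.30, Clic6 at -0.84 ± 0.24, Kcne2 at -0.78 ± 0.21 and Slc4a5 at -0.65 ± 0.19. The list mean was -0.46 within numbers 1 to 4 and -0.50 within 5 to 7. Microglial markers were higher, with 13 of 14 positive and a mean of +0.24 (adjusted p = 4.03e-05, and adjusted p = 0.536 with an estimated correlation). Among them Cx3cr1, the fractalkine receptor gene, was at +0.53 ± 0.18 (+0.30 without PBS array 2) and P2ry12 at +0.32 ± 0.096. PBS array 2, lowest in these markers, set much of that difference, and without it the mean was +0.08 (adjusted p = 0.0207). Over all alternatives adjusted p ran from 2.43e-07 to 0.536 for microglial and from 1.10e-05 to 0.536 for choroid plexus markers.

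Pericyte markers were lower by a mean of -0.17, with 12 of 14 negative (camera adjusted p = 0.0293, and adjusted p = 0.733 with an estimated correlation). Kcnj8 and Abcc9, which encode the ATP-sensitive potassium channel of pericytes, were at -0.21 ± 0.060 and -0.35 ± 0.14. The call was lost without PDGF-CC arrays 1 (mean -0.10, adjusted p = 0.179) and 2 (0.0876) and without PBS arrays 1 (0.106) and 3 (mean -0.10, 0.254). It was also lost with the filter at the 50th percentile (0.0566), with array weights (0.0785) and with description number as a covariate (mean -0.09, 0.0676), and the alternatives ran from 0.000452 to 0.733. Lymphocyte markers were higher by a mean of +0.14, with 5 of 7 positive (adjusted p = 0.0356, and adjusted p = 0.536 with an estimated correlation). Ptprcap was at +0.34 ± 0.13. Levels were low, with PBS means of 5.02 for Ptprcap and 4.45 for Cd3d, against a filter of 4.145. The lymphocyte call was lost without PDGF-CC arrays 1 (adjusted p = 0.0610) and 2 (0.0784) and without PBS arrays 1 (0.101) and 3 (0.193). It was also lost without the filter on brightness (mean +0.08, 0.168), with repeated quantile normalization (0.111) and with description number as a covariate (0.0719), and the alternatives ran from 0.0118 to 0.536. In all, camera called 12 of 37 lists, 8 lower and 4 higher, of which 4 were of the 13 cell type lists. With an estimated correlation, and with fry's directional test, 0 lists were called, and fry's test for change in either direction called 2, the glucocorticoid and PDGF lists. With the preset correlation, camera called 7 lists without PBS array 1, of which 2 were cell types, and without PDGF-CC array 2 also 2 cell types. For the means of the lists called with all arrays, exact permutation p was 0.0286 for glucocorticoid, microglia and lymphocytes. It was 0.0571 for immediate-early and choroid plexus, and 0.0857 for respiratory chain, ribosomal and heat shock. For hypoxia it was 0.143, for interferon 0.2, for TGF-beta 0.229 and for pericytes 0.257. Adjusted over the 37 lists, none was below 0.352.

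**Figure D2:**
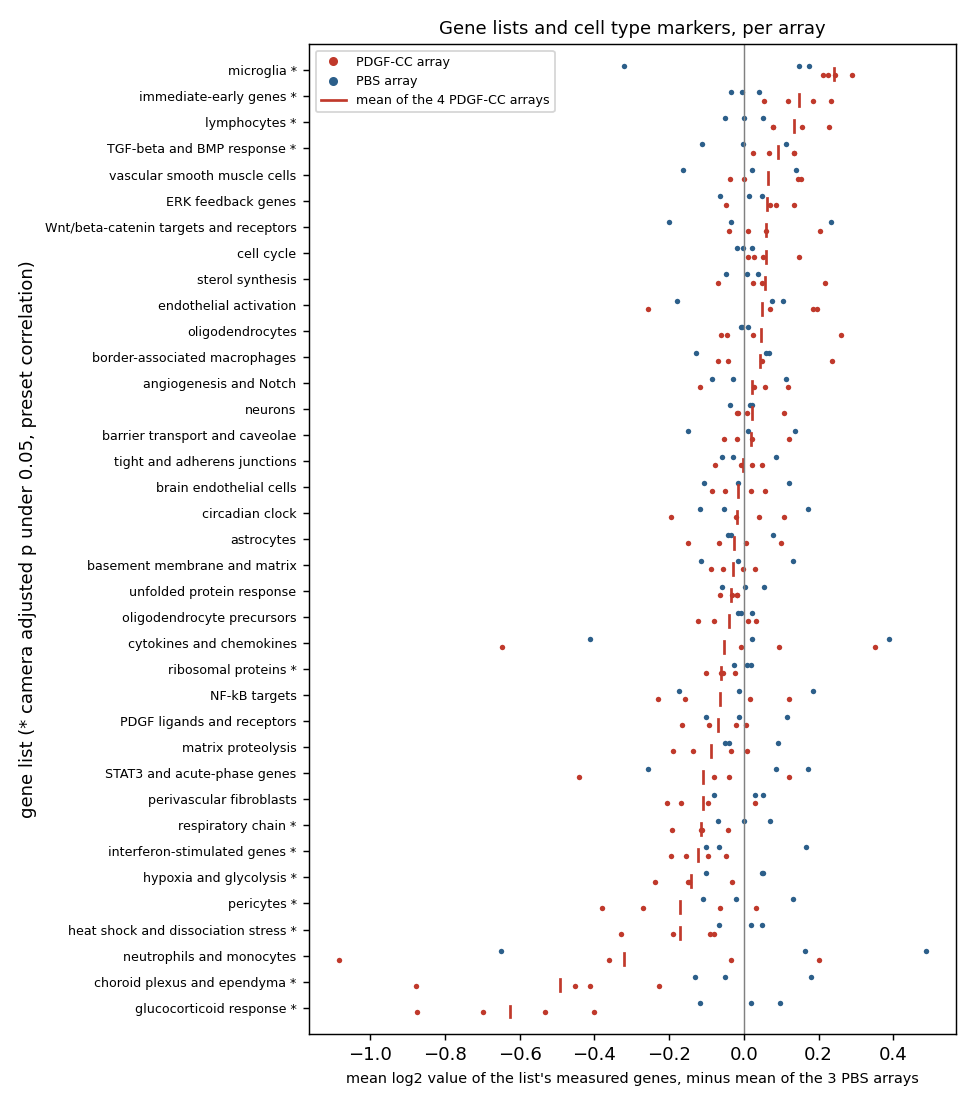
Mean log2 value of each list's measured genes in every array, minus the mean of the 3 PBS arrays, for the 37 lists tested; red points are PDGF-CC arrays, blue points PBS arrays, red bars the PDGF-CC mean, and asterisks mark camera's calls with the preset correlation. The glucocorticoid list lies lowest, with a PDGF-CC mean of -0.63, and the microglia list highest, at +0.24, where a single PBS array lies at -0.32.

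Markers of the remaining cell types did not pass the test with all arrays, although single arrays decided several of these results. Brain endothelial markers had a mean of -0.02 (camera adjusted p = 0.408), with 8 of 19 positive. The transporter gene Slco1a4 was at -0.13 ± 0.066 and Ly6c1 at -0.16 ± 0.074, while Egfl7 was at +0.20 ± 0.10. Without PBS array 3 Slco1a4 was at -0.08 and Egfl7 at +0.32, and without PBS array 2 Egfl7 was at +0.12. Smooth muscle markers had a mean of +0.07 (adjusted p = 0.270), with Cnn1 at +0.21 ± 0.059, and perivascular fibroblast markers -0.11 (0.248), with Dcn at -0.47 ± 0.14. Astrocyte markers were at -0.03 (0.525), neurons at +0.02 (0.913), oligodendrocytes at +0.04 (0.270) and their precursors at -0.04 (0.944). Border-associated macrophages were at +0.04 (0.544). Neutrophil and monocyte markers had a mean of -0.32 (0.185), with an SD of 0.56 between PDGF-CC arrays and 0.59 between PBS arrays. Their Ly6c2 was at -0.32 ± 0.087, with a PBS mean of 9.59, far above those of Cxcr2 (6.30), Mmp9 (4.76) and Ltf (4.46). That list was called lower without PDGF-CC array 1 (mean -0.49, adjusted p = 0.0247), without PBS array 3 (mean -0.64, 0.00383), with array weights (0.0127) and with description number as a covariate (1.68e-06), in a range up to 0.902. Endothelial markers were called lower without PBS array 2 (mean -0.07, 0.0248), with means up to +0.05 without other arrays. Smooth muscle markers were called higher without PBS array 3 (mean +0.14, 0.0272), with array weights (0.0315) and with description number (0.00753), and were at -0.02 without PBS array 1. Fibroblast markers were called lower without PDGF-CC array 4 (mean -0.16, 0.0287).

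Genes of the blood-brain barrier and of vascular inflammation were not called as lists. Tight and adherens junction genes had a mean of -0.003 (camera adjusted p = 0.632), with Ctnnb1 at -0.13 ± 0.080 (-0.04 without PBS array 3) and Jam2 at -0.13 ± 0.066. Barrier transport genes were at +0.02 (0.676), with the transferrin receptor gene Tfrc at +0.63 ± 0.20. Basement membrane genes were at -0.03 (0.676) and matrix proteolysis genes at -0.09 (0.676). In the latter, Plau, which encodes urokinase, was at +0.34 ± 0.075 and was 1 gene higher adjusted over the list alone, against 0 over all genes. Wnt genes had a mean of +0.06 (0.255), with the receptor gene Fzd4 at -0.55 ± 0.15. That list was called higher without PBS array 3 (mean +0.18, adjusted p = 0.000688) and with description number as a covariate (0.00987), and was at -0.04 without PBS array 2, in a range up to 0.952. Angiogenesis and Notch genes had a mean of +0.02 (0.961), with Dll4 at +0.31 ± 0.10. Endothelial activation genes had a mean of +0.05 (0.787), with Sele, encoding E-selectin, at +0.72 ± 0.50 (+0.33 without PBS array 3 and +1.12 without PDGF-CC array 4).

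Cytokines and chemokines had a mean of -0.05 (camera adjusted p = 0.950), with 8 of 22 positive and 14 negative. Tnf was at +1.20 ± 0.45, Ccl3 at +0.58 ± 0.22 and Csf1 at +0.37 ± 0.10. Cxcl1 was at -0.66 ± 0.36 (-0.28 without PBS array 2). That list was called higher without PDGF-CC array 4 (mean +0.15, adjusted p = 0.0473), in a range of 0.0416 to 0.997 over all alternatives. NF-kB targets had a mean of -0.06 (0.904). Adjusted over the list alone, Bcl3 was higher (+0.40 ± 0.087) and Nfkbia, the inhibitor of NF-kB, lower (-0.56 ± 0.12). Bcl3 was also the 1 member past the list-alone threshold among STAT3 and acute-phase genes, whose mean was -0.11 (0.525). The sterol synthesis list had a mean of +0.06 (0.185), with a call only without PDGF-CC array 2 (mean +0.10, 0.0283), the cell cycle list +0.06 (0.210), the unfolded protein response list -0.03 (0.632) and the circadian clock list -0.02 (0.708). Named cell cycle genes were low, with PBS means of 4.06 for Aurkb, 4.11 for Top2a, 4.68 for Cdk1 and 5.05 for Ccnb2. Mean, median and test differed in sign for the unfolded protein, basement membrane, barrier transport, circadian, cytokine, oligodendrocyte precursor and angiogenesis lists, none of which was called.

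**Figure D3:**
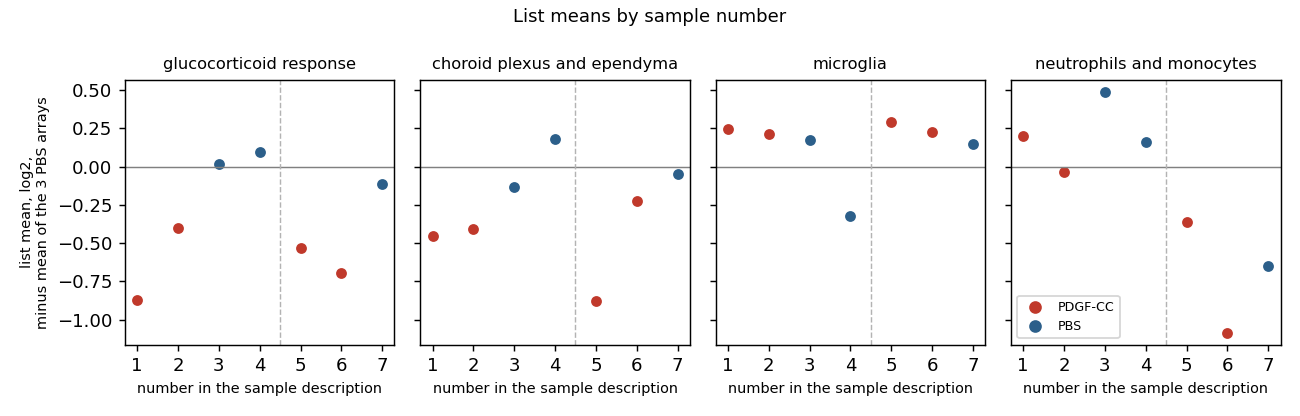
Mean log2 value of 4 lists, minus the mean of the 3 PBS arrays, against the number in the sample description; red points are PDGF-CC arrays, blue points PBS arrays, and the dashed line parts numbers 1 to 4 from 5 to 7. The glucocorticoid list is lower in PDGF-CC on both sides of the line, while neutrophil and monocyte markers are lower in numbers 5 to 7, where their means run from -0.36 to -1.08. On each side the PDGF-CC arrays have the lower numbers, so treatment and order cannot be told apart there.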

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

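In the PDGF-CC group, 200 sets of 4 arrays (each named probe set and each list mean) were examined for an array far from the others, and 21 stood out, where chance gives about 1 in 20 groups, or 10. The measure is the gap from the farthest array to its nearest neighbour, divided by the range, set against Dixon's critical value. Groups of 3 arrays, such as PBS, were not examined. In 12 of the 21, at least 2 of the 4 arrays held exactly the same value, against 32 of all 200. Sets without equal values stood out at about the chance rate of 1 in 20, so the excess lay in the sets with equal values.

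PDGF-CC array 4 was lowest for Sele (ratio 0.883, gap 1.52 log2), Timp1 (0.849, gap 1.01), Cxcr2 (0.856), Asns (0.869), Cnn1 (0.939), Pdk4 (0.935) and Trib3 (1, with a gap of 0.00668), and highest for Fmod (0.845). PDGF-CC array 1 was lowest for Mmp9 (0.960, gap 0.769), Ifit1 (0.896) and Ntsr2 (0.938), and highest for Cnp (0.988), Cd79b (0.936) and Lrp1 (0.885). PDGF-CC array 2 was highest for Bcl3 (0.923), Pfkfb3 (0.900) and Fgfr3 (1), and lowest for Hspg2 (0.902) and Rps26 (0.887). PDGF-CC array 3 was highest for Fdps (0.894) and lowest for Lamb1 (0.833). No list mean was among them.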

How the results depend on the processing

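One alternative, description numbers 1 to 4 against 5 to 7 as a block, was chosen after seeing the data. Of 3077 values of 163 named probe sets under the alternatives, 3055 kept their direction and side of the threshold, 14 came to pass it and 8 turned. None of these probe sets passed in the main fit, so keeping the side meant staying uncalled and no call could be lost. Of the 14, 3 passed only because the threshold itself was loosened to 0.10. Of 663 list values, 548 kept both, 58 lost the call, 13 gained one and 44 turned, all of these in lists that camera did not call with all arrays. Of the 44, 2 were called, both of the cytokine list, with the title number as a block and without PDGF-CC array 4. Both rest on the same estimate (mean 0.145), so they do not count as separate results. Without 1 array, 75 of the 163 named probe sets moved by over 1.5 times or turned in at least 1 case. With camera at the preset correlation, the glucocorticoid, choroid plexus, microglia, respiratory chain, ribosomal and heat shock calls held without any 1 of the 7 arrays. Its p-values rest less on the spread between samples, so leaving out an array is a weak test of them. All of these calls were lost with an estimated correlation and with fry's directional test. The cause of the changes below was not tested unless given.

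The number of called probe sets, 0, became 3 with the filter at the 50th percentile, with a trended and robust prior, with median centring and at an adjusted p under 0.10, and 1 with repeated quantile normalization, all lower. It ran from 0 to 1 without 1 array. Adjusted p ranged from 0.031 to 0.438 for Cdkn1a and from 0.031 to 0.428 for Trp53inp1. The looser count, 47, became 75 with all rows and no filter (more probe sets tested) and 73 with the description number as a covariate, and ran from 30 to 62 without 1 array. With the added block it was 65, with 0 called. Lists called, 12, and cell type lists called, 4, both became 0 with an estimated correlation and with fry's directional test, cell types became 2 at the 50th percentile, and without 1 array they ran from 7 to 13 and from 2 to 5.

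With the title number as a replicate block, the looser count became 87, with 0 probe sets and 12 lists called, of which 10 were among the 12 called without it. The TGF-beta (adjusted p = 0.0915) and hypoxia (0.0951) lists were not called, and the cytokine and perivascular fibroblast (0.0326) lists were. Same-numbered arrays deviated together at r of 0.163, 0.107 and 0.0844, not all over 0.1. PBS arrays 1 and 2 correlated best with the PDGF-CC arrays of their own number and PBS array 3 with PDGF-CC array 4, so the numbers were not treated as pairs. The block takes nothing from PDGF-CC array 4, whose number has no PBS array, so its list means equal those without that array. List means that turned under it were barrier transport (-0.0154), cytokines (0.145, called at adjusted p = 0.0416, where the other alternatives gave 0.0473 to 0.997), STAT3 (0.000883) and angiogenesis (-0.0108).

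Tight junctions turned with array weights (0.00848), quantile normalization (0.0227), median centring (0.00685), description number (0.0229) and averaged probe sets (0.000775). The clock list turned with array weights (0.0171), as did Sdf2l1 (-0.0214). With description number, the clock (0.0463), endothelial (0.0225), endothelial activation (-0.0160), basement membrane (0.00561) and neuron (-0.000757) lists and Pdgfrb (0.0555) turned. Endothelial markers also turned with quantile normalization (0.0305). With the added block, barrier transport (-0.00555), cytokines (0.0435) and angiogenesis (-0.00280) turned.

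Without 1 array, means ran from -0.0323 to 0.0401 (tight junctions), -0.0762 to 0.0674 (clock), -0.0692 to 0.0456 (endothelial), -0.0555 to 0.0874 (barrier transport), -0.258 to 0.145 (cytokines), -0.237 to 0.000883 (STAT3), -0.0205 to 0.0780 (angiogenesis), -0.0416 to 0.150 (endothelial activation), -0.0865 to 0.0374 (basement membrane), -0.00779 to 0.0334 (neurons), -0.0691 to 0.0137 (astrocytes), -0.0268 to 0.0800 (oligodendrocytes), -0.0215 to 0.0802 (border-associated macrophages), -0.0158 to 0.135 (smooth muscle), -0.0410 to 0.176 (Wnt) and -0.150 to 0.0300 (NF-kB). Others moved by over 1.5 times without turning, from 0.0293 to 0.0974 (ERK feedback), -0.119 to -0.0107 (PDGF), -0.119 to -0.0418 (matrix proteolysis), 0.0295 to 0.0749 (cell cycle), -0.0626 to -0.00604 (unfolded protein), 0.00149 to 0.0968 (sterol), -0.0640 to -0.0123 (oligodendrocyte precursors) and -0.645 to -0.0646 (neutrophils and monocytes). Differences ran from -0.0499 to 0.163 for Sdf2l1, -0.248 to 0.142 for Pdgfrb, -0.00319 to 0.255 for Lrp1, -0.0145 to 0.0427 for Pdgfc and -0.106 to 0.0256 for Trib3.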

Other observations

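The tests on description numbers, on splits of the arrays and on explanations were chosen after the results were seen, while the counts for PDGF-CC against PBS, the fixed lists and median centring were planned. The arrays also parted by the number in the sample description, across both groups, and on the first principal component they ran in the order of that number. With treatment in the model, numbers 5 to 7 against 1 to 4 gave 1 called probe set, Chil3, a gene of myeloid cells, at -2.23 ± 0.118 (SE, limma adjusted p = 0.0198), chosen after its values were seen. Neutrophil and monocyte markers were lower in numbers 5 to 7 by a mean of -0.903, and cytokines by -0.569. Brain endothelial markers were higher by 0.130. Each of these 3 means was the largest of the 35 splits (exact permutation p = 0.0286, without adjustment over lists). Pericyte markers were higher by 0.229 (exact permutation p = 0.114) and microglial markers by 0.143 (exact permutation p = 0.600).

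By limma, 0 probe sets were called in total, higher or lower. At an unadjusted p under 0.05 there were 1071, where chance gives 887, and at a p under 0.01 there were 190, where chance gives 177. A count of 0 is matched by all 35 splits whatever the data, so the splits say nothing about it, and the highest other split gave 1 in total, 1 higher and 0 lower. Chance could not be excluded for the looser count or for the counts of lists. The 47 probe sets of the looser count were matched or passed by 3 of the 35 splits, the real one included, and the highest of the others was 66. That split sets PDGF-CC arrays 3 and 4 and PBS array 3 apart, which are description numbers 5 to 7. With these numbers as a block, the looser count was 65 and 0 probe sets were called. The 12 lists were matched by 6 splits (highest other 18) and the 4 cell type lists by 10 (highest other 6).

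Centring each array on its median left the mean of the lower glucocorticoid list at -0.616, but it moved all genes by little, so it does not test whether the normalization between arrays bears on it. Less glucocorticoid hormone in the animals given PDGF-CC is a candidate explanation, whether from the treatment or from handling. The 11 members that are not on a list of FOXO targets had a mean of -0.494, which 2 of 35 splits matched (exact permutation p = 0.0571). This cannot be told apart from an effect of PDGF-CC on these genes, because no hormone level was used here. Heavier dissociation stress in the PBS samples stays open too: heat shock genes were lower in PDGF-CC (-0.172), while immediate-early genes were higher (0.147).

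The lower choroid plexus markers may come from less choroid plexus tissue in the PDGF-CC samples. The 8 choroid plexus markers, of which 7 were lower, varied together between arrays of a group, with a mean pairwise correlation of 0.720 after group means were removed. Ttr, an abundant choroid plexus transcript chosen after its values were seen, had a PBS mean of 12.9, near the top of the range of the arrays. Its difference was therefore not read alone, but Ttr stayed among the 8 markers and in the list, so the values here include it. Lowering of these genes by PDGF-CC itself, with a list median of -0.563, cannot be told apart from less tissue, because tissue content and treatment both follow the groups.

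The split by description number may follow leukocyte content, given the neutrophil and monocyte difference of -0.903, although that list was picked among 37 after the values were seen. Time of day is another candidate explanation, and 8 clock output genes were higher in numbers 5 to 7 by 0.375, which 2 of 35 splits matched (exact permutation p = 0.0571). The labels do not say what the numbers stand for, so the design gave no explanation to test.

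Several of the lower genes (Cdkn1a, Sesn1, Trp53inp1, Depp1, Angptl4, Pdk4) are textbook targets of FOXO factors, of p53 or of PPAR nuclear receptors, which raised the hypothesis that one of these programmes might be lower after PDGF-CC. Target genes not already named were therefore tested by exact permutation over the 35 splits, with adjustment over 4 lists. The 29 FOXO targets had a mean of -0.0899 (exact p = 0.114, adjusted 0.190) and the 23 p53 targets of -0.0483 (exact p = 0.143, adjusted 0.190). The 20 PPAR targets had a mean of -0.101, the largest of the 35 splits (exact p = 0.0286, adjusted 0.114), and the adjustment over 4 lists was added after that value was seen. No adjusted value could pass 0.05 for a single list in this design, so none of these hypotheses was decided. Clock output genes, tested for a difference in phase between the groups, were at 0.0373, which 29 of the 35 splits matched, with SDs of 0.242 and 0.275 between arrays.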
